A study of Mus musculus with 4 samples.

How the data were processed

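The data were 4 arrays of total RNA from mouse distal colon, 1 for each combination of genotype (WT or Adamts12 KO) and treatment (untreated or 2% DSS). Per the labels' protocols, mice were 8 to 10 weeks old at the start, RNA was extracted with Trizol, and biotinylated cRNA was prepared and hybridised to Affymetrix arrays. The deposited table held 45101 probe sets with values on a log scale from 0.16 to 13.23. The authors' deposited values were taken as log2, because a natural log would put the top value at 556821, above the 65535 that a 16-bit scanner can give, while log2 puts it at 9608. The method of summarization and normalization is not given in the sources used here. The columns had nearly equal quantiles, with medians of 3.42 to 3.46, and were used as deposited. The precision is limited by the number of arrays, and background, scanner files and probe-level detection calls were not used here.

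Probe sets were named through the platform's annotation table, with symbols updated by Entrez gene number through a RefSeq gene table of assembly GRCm38.p6, used only for names and gene order. Of the probe sets, 64 were controls, 34945 had 1 symbol, of which 34741 matched by gene number, 932 had several symbols and 9160 were unnamed. Only those with 1 symbol were used for genes. A probe set was kept when it lay above its array's median on at least 1 of the 4 arrays, which left 24602, 21125 of them with 1 symbol. A gene was represented by its kept probe set with the highest mean over the 4 arrays, giving 12189 genes, 5420 of which had more than 1 kept probe set. The genome build behind the annotation is not given in the sources used here, so no coordinates are printed.

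Comparisons within a pair of arrays were log2 differences and counts of genes at least 2-fold apart, with no test. DSS against untreated (with genotype as covariate) and KO against WT (with treatment as covariate) were tested over the 4 arrays with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The model had 1 residual degree of freedom and a median of 2.68 prior degrees of freedom. The labels give 1 mouse per group, so the spread in these tests is how far the effect of 1 factor differed between the levels of the other.

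The groups, comparisons, alternatives, rule for named genes and 38 gene lists were set before the data were examined. The lists came from textbook knowledge. They cover inflammation (neutrophil markers, chemokines, inflammatory cytokines, antimicrobial and acute-phase, interferon-stimulated and MHC class II genes), matrix turnover, epithelial states and lineages, other cell types, metabolism, stress and handling, the circadian clock, neighbouring tissue, position along the gut, sex-linked genes, neighbours of Adamts12 and housekeeping genes. For each list, members at least 2-fold higher or lower were counted, and the median log2 difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. For the limma tests, members were also adjusted over the list alone, in 38 lists for each of 2 model terms, with no correction for that number of lists. Named genes were Adamts12, the 12 highest and 12 lowest mean DSS differences among genes at least 2-fold apart the same way in both genotypes, the 10 highest and 10 lowest mean KO minus WT differences chosen likewise over both treatments, the 8 highest and 8 lowest of KO against WT in each treatment and of the difference of the DSS effect, and up to 4 members of each list described, or all where a count was 5 or fewer. Gene models without a name of their own were left out of the rankings. Genes of the lists named for their adjusted test followed from that test. The 14 genes drawn on each array were chosen after their values were seen.

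The code was tested on simulated data. With a spread drawn as in these arrays, limma called 0% of 50 genes simulated with a DSS change of 1 on the log2 scale, 0% at 2, 60% at 4 and 94% at 6. It made 9 false calls among the unchanged of the 12189 genes. With a lower variance that was the same for every gene, limma called 100% at each size. The simulated spread did not depend on the size of the change. Among these arrays, genes with large DSS differences such as Cxcl5 and S100a9 had SEs of 0.84 and 0.98, so the simulated shares may not hold. Of 200 simulated lists of 20 genes with no shift, 2.5% lay above percentile 97.5, and 98.0% did with a shift of 0.5.

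Alternatives were quantile normalization, median centring, no filter, a filter at the 75th percentile, the mean over a gene's probe sets, leaving out probe sets that can match several transcripts, limma without the covariate or the trend, an added 2-fold threshold and leaving out each array. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. The 18 hybridization controls, which monitor brightness, differed from the untreated WT array by a median of -0.66 on the untreated KO, -0.32 on the WT DSS and -0.12 on the KO DSS array. The 2 poly-A controls above the array medians differed from the untreated WT array by medians of -1.40, -0.88 and 0.00 on these arrays in that order. The 3' minus 5' log2 difference, a sign of RNA integrity, was 0.64 to 0.83 for the actin control, 0.16 to 0.26 for the Gapdh control and 2.16 to 2.47 for the transferrin receptor control. It was 2.82 on the untreated WT, 1.67 on the untreated KO, 2.20 on the WT DSS and 2.11 on the KO DSS array for the pyruvate carboxylase control.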

Results

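Gene expression was measured in the distal colon of 4 mice on Affymetrix mouse expression arrays, with 1 array per mouse. Adamts12 encodes a secreted metalloprotease of the ADAMTS family, and the mice were either wild type (WT) or deficient in it (KO). Dextran sodium sulfate (DSS), a polymer that injures the colonic epithelium and causes colitis, was given at 2% in the drinking water to 1 mouse of each genotype, and 1 mouse of each genotype was left untreated. The labels differ on the length of the treatment, which is given as 7 days in the series text and as 8 days in the treatment protocol, each followed by 1 day without DSS. The design asks how the colon responds to DSS, whether loss of Adamts12 changes expression in the untreated colon, and whether it changes the response to DSS. With 1 array in each of the 4 groups, the number of arrays limits the precision, and a difference between a pair of arrays has no replicate check.

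After the filter on dim probe sets, 12189 genes were compared. Across these genes, which are not independent replicates, the WT and KO DSS arrays were the most alike (Pearson r = 0.960), and the untreated and DSS KO arrays the least alike (r = 0.873). The untreated WT array correlated at 0.920 with the untreated KO array and at 0.933 with the WT DSS array. The column medians of all probe sets lay between 3.42 and 3.46 on the log2 scale. Values at or under 1.39, the highest value of 9 Y-linked probe sets on arrays where Xist was bright, were read as not above background, a limit set after the values were seen. A difference from such a value is given as a bound, the distance to 1.39, while rankings, medians and counts use the measured values.

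The targeted gene was examined first. The brighter of the 2 Adamts12 probe sets (1439827_at) had a log2 value of 2.18 on both WT arrays, and of 1.42 on the untreated and 1.41 on the DSS KO array. The KO minus WT difference was -0.76 without DSS and -0.77 with DSS, in the direction of the labels. The other probe set (1446666_at) lay between 0.71 and 0.97 on all 4 arrays, not above background. Both were dim, at percentile 32.6 or lower of the probe sets of each array, and the labels do not say which part of the gene was removed, so these values check the genotypes only weakly.

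The genes with the highest mean DSS difference over the genotypes included neutrophil, chemokine and tissue-remodelling genes. Cxcl5, a chemokine that attracts neutrophils, was higher by 4.58 in WT and by at least 7.21 in KO on the log2 scale. S100a8 and S100a9, which encode the subunits of the neutrophil protein calprotectin, were higher by 4.20 and 2.80 in WT and by 6.41 and 6.44 in KO. The matrix metalloprotease genes Mmp3 and Mmp13 were higher by 3.66 and 1.39 in WT and by 6.63 and 5.40 in KO. Lrg1, a secreted glycoprotein of the acute-phase response, differed almost equally, by 5.22 in WT and 5.18 in KO.

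The other genes with the highest mean DSS difference were the chemokines Cxcl2 (3.38 in WT, 5.62 in KO) and Cxcl3 (at least 1.81 and 3.42), the growth factor gene Ereg (2.96 and 4.92), Clca4b (1.55 and 6.95), the hyaluronan-degrading Cemip (2.01 and 5.39) and Anxa8 (1.84 and 5.13). The rises of Clca4b and Anxa8 in KO started from low values on the untreated KO array, 3.95 and 3.55. On the untreated WT array they were at 9.02 and 6.16. The lowest mean DSS differences included those of several enzyme genes. The deiodinase gene Dio1 differed by -3.72 in WT and -3.70 in KO, the gluconeogenic enzyme gene Pck1 by -2.89 and -3.57, and the sulfotransferase gene Sult1a1 by -2.40 and -4.27. Cyp2c55, a cytochrome P450 gene, differed by -1.56 in WT and -9.12 in KO. Its drop in KO started from 11.13 on the untreated KO array, against 4.49 on the untreated WT array. The DSS arrays lay at 2.93 in WT and 2.01 in KO. Also among the 12 lowest were Edn2 (lower by at least 2.59 in WT, -4.09 in KO), Hsd3b3 (-1.04 and -4.91), Fmo5 (-1.60 and -4.25), Clps (-3.99 and -1.84), Mep1a (-1.30 and -4.29), Anxa13 (-2.42 and -3.14) and Pla2g4c (-1.94 and -3.40). Xaf1 differed by -4.32 and -1.91, but its other probe set went the opposite way, with a mean DSS difference of 0.68.

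At least 2-fold differences with DSS were seen for 709 genes higher and 605 lower in WT, and for 1312 higher and 814 lower in KO. Of these, 302 were higher in both genotypes, where 76.3 would be shared by independent lists, and 161 were lower in both, against 40.4. Another 98 genes were lower in WT and higher in KO, against 65.1, and 41 went the other way, against 47.4. Across all genes, the DSS differences in WT and KO correlated at r = 0.255 (Spearman's rho = 0.266).

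**Figure D1:**
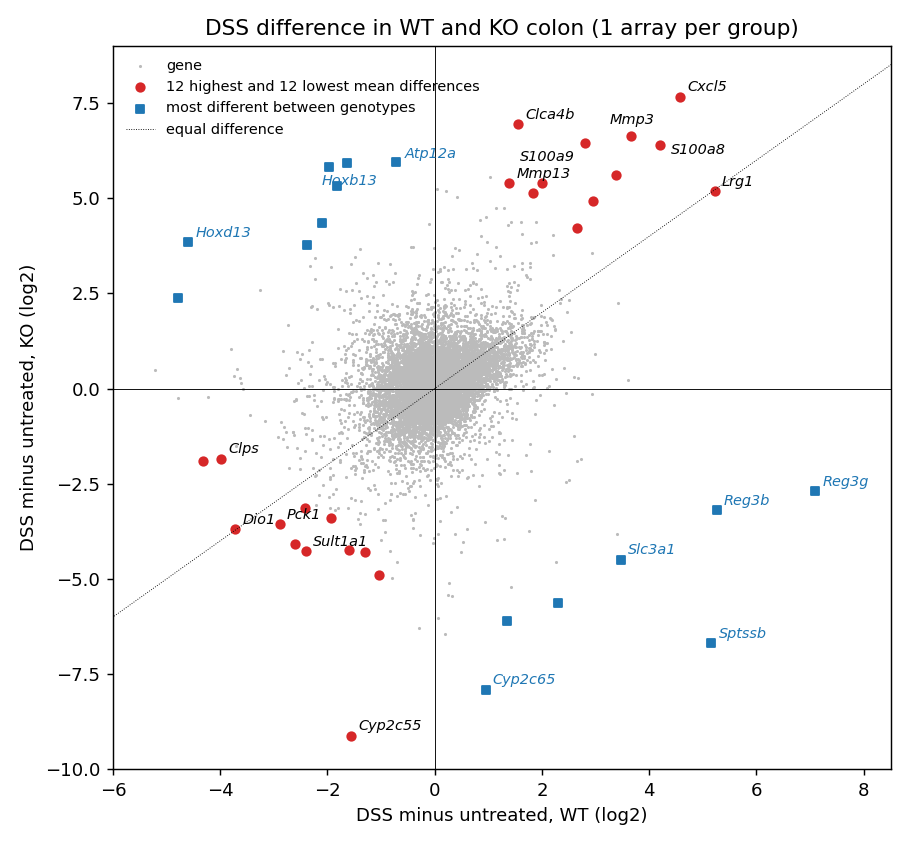
Log2 difference between the DSS and the untreated array in WT (horizontal) and in KO (vertical) for each of 12189 genes, with 1 array per group and so no error bars. Red points are the 12 genes with the highest and the 12 with the lowest mean difference, such as Lrg1 at 5.22 and 5.18 near the line of equal difference. Blue squares are other genes whose differences in WT and KO were farthest apart, such as Reg3g at 7.09 and -2.70.

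All measured proliferation genes were higher with DSS in both genotypes. Of 21 measured, 19 were at least 2-fold higher with DSS in WT and 15 in KO, none was 2-fold lower, and the median log2 differences were 1.61 and 1.36. Rrm2, a subunit of ribonucleotide reductase, was higher by 2.31 and 2.58, and the replication helicase gene Mcm3 by 2.18 and 1.81. In limma's additive model over the 4 arrays, 20 of the 21 passed the test adjusted over the list alone and 0 passed over all genes.

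The neutrophil, inflammatory cytokine and protease lists had higher medians with DSS in both genotypes, by a wider margin in KO, and the chemokine list in KO. Members that passed the filter only through the KO DSS array, such as Il6, could only be higher there. Of 11 neutrophil markers, 3 were at least 2-fold higher in WT (S100a8, S100a9 and Ltf) and 8 in KO, with medians of 0.57 and 1.27. Of 10 inflammatory cytokine genes, 3 were higher in WT (Il1b, Il33 and Lif) and 9 in KO, with medians of 0.35 and 2.79. Il6 was not above background on either WT array and was higher by at least 4.89 in KO. Il1b was higher by 1.63 in WT and 3.31 in KO, and Il33 by 1.14 and 4.75. Of 24 chemokine genes, 5 were higher in WT (Cxcl1, Cxcl2, Cxcl3, Cxcl5 and Cxcl11) and 3 lower (Cxcl12, Ccl20 and Ccl28), with a median of 0.09 (percentile 82.5 of matched random lists). In KO, 13 were higher and 4 lower (Ccl5, Ccl9, Ccl12 and Ccl25), with a median of 1.10. Of 16 genes of matrix-degrading proteases and their inhibitors, 6 were higher in WT, and 10 higher and 1 lower (Mmp7) in KO, with medians of 0.53 and 1.46. Genes of the fetal-like repair epithelium, a state seen in regenerating gut, had medians of 0.48 in WT and 2.00 in KO over 16 genes, with Ptgs2 at 1.04 and 5.56. The KO minus WT median of that list was -0.93 without and 0.92 with DSS. Of 20 epithelial antimicrobial and acute-phase genes, 10 were higher and 4 lower in WT (Reg4, Saa1, Saa2 and Pigr), and 11 higher and 3 lower in KO (Reg3b, Reg3g and Ang4), with medians of 0.75 and 1.40. Within that list, Pla2g2a was higher by 2.93 and 3.55, while the lectin genes Reg3g and Reg3b were higher in WT by 7.09 and 5.26 and lower in KO, by -2.70 and -3.20. The drop in KO started from high values on the untreated KO array, 9.37 for Reg3g and 11.01 for Reg3b, against 4.01 and 6.60 on the untreated WT array. The KO DSS array, at 6.67 and 7.81, lay above the untreated WT array.

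The goblet cell, colonocyte transport and xenobiotic lists had lower medians with DSS in both genotypes. Of 19 goblet cell genes, 8 were at least 2-fold lower in WT and 9 in KO and 0 were 2-fold higher, with medians of -0.50 and -0.59. Klk1 differed by -1.84 and -2.65, and Atoh1, a transcription factor of the secretory lineage, by -1.32 and -2.15. Of 30 genes of colonocyte transport and absorption, 12 were lower and 2 higher in WT (Slc9a3 and Ces1f), with a median of -0.73. In KO, 14 were lower and 5 higher (Aqp8, Aqp4, Atp12a, Fxyd4 and Slc37a2), with a median of -0.63. Of 23 xenobiotic and detoxification genes, 8 were lower and 3 higher in WT (Gsta3, Nqo1 and Gpx2), and 14 lower and 1 higher in KO (Gpx2), with medians of -0.59 and -1.82. Genes of fatty acid oxidation, ketogenesis and PPAR targets had medians of -0.14 in WT (percentile 12.6) and -0.94 in KO (percentile 0) over 21 genes, with Ppara at -0.97 and -3.46. The wider drop of the xenobiotic and fatty acid lists in KO started in part from higher values on the untreated KO array. Their KO minus WT medians were 0.52 and 0.61 without DSS, and -0.30 and -0.25 with DSS.

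Over all genes, limma's test of DSS against untreated found 0 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1437 genes (931 higher, 506 lower), where 609 would be found by chance, and 2091 without the covariate. The smallest adjusted p was 0.364, for Lrg1 (log2 difference 5.20, SE 0.23, higher in both genotypes). Adjusted over the list alone, the genes past the test were S100a8 among neutrophil markers, Cxcl2 and Cxcl5 among chemokines, Mmp3, Mmp10, Timp1 and Plaur among proteases and inhibitors, and Ereg, Hbegf, Sprr1a and Plaur among fetal-like repair genes, all higher. In the antimicrobial list Saa3, Duoxa2, Nos2, Pla2g2a, Hp and Lbp were higher and Pigr lower, among goblet cell genes Atoh1, Bcas1, Capn9 and Klk1 were lower, and among xenobiotic genes Gpx2 was higher and Cyp2s1 and Cyp3a13 lower. Mcpt1 and Mcpt2 were higher and Kit lower among mast cell and eosinophil markers, and Hsp90aa1, Hspe1 and Hspd1 were higher among heat shock genes. The model takes any difference of the DSS effect between the genotypes as error and has 1 residual degree of freedom. The untreated KO array, which enters the DSS difference in KO, stood apart in genes that mark position along the colon, and 748 genes in place of 1312 were at least 2-fold higher when the KO DSS array was set against the untreated WT array, a comparison chosen after seeing the data.

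**Figure D2:**
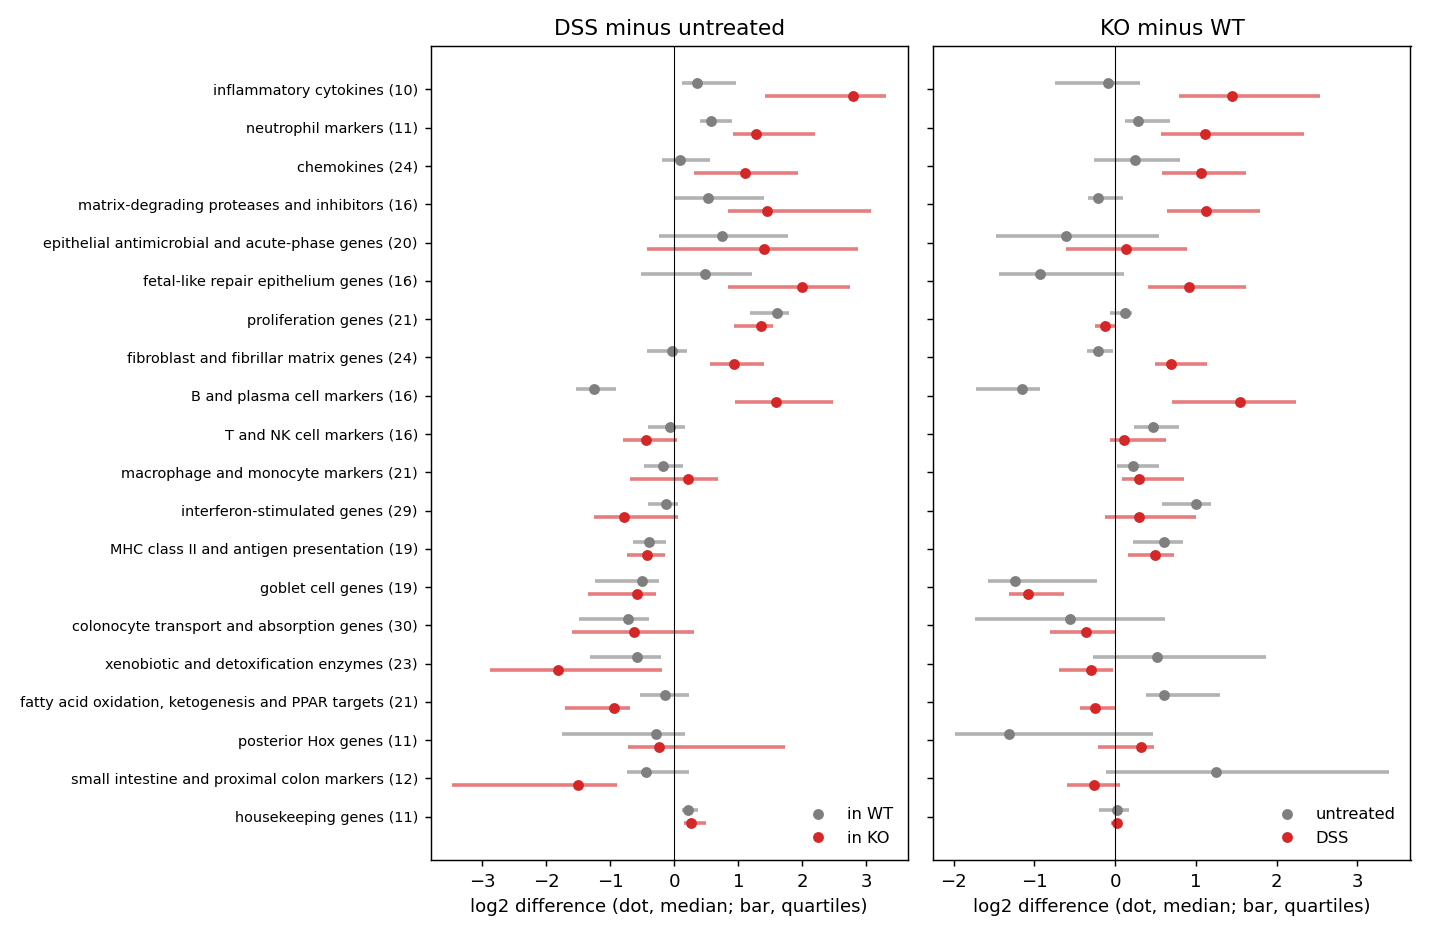
Median log2 difference (dot) and quartiles over members (bar) of 20 gene lists fixed before the data were examined, with the number of measured members in brackets. The left panel shows DSS minus untreated in WT and KO, and the right panel KO minus WT without and with DSS. Inflammatory cytokine genes lay at 0.35 in WT and 2.79 in KO with DSS, and B and plasma cell markers lay on opposite sides of 0 in both panels.

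Without DSS, the KO colon had low levels of several genes that were bright in the WT colon, and the reverse. Sval1 (-7.96), the pentraxin gene Mptx1 (-7.18), the posterior homeobox genes Hoxb13 (-6.99) and Hoxd13 (-5.46), the proton pump gene Atp12a (-6.85), Reg4 (-6.40), Tgm3 (-5.40) and the hormone gene Insl5 (-5.12) had the lowest KO minus WT log2 differences. The highest were those of Cyp2c55 (6.64), the transcription factor gene Osr2 (at least 6.28), Cyp2c65 (6.41), Sptssb (6.13), the glucuronosyltransferase gene Ugt2b5 (at least 5.68), the bile acid transporter gene Slc51a (5.86), the sulfate transporter gene Slc13a1 (5.84) and the intestinal homeobox gene Isx (5.66). In all, 418 genes were at least 2-fold higher and 730 at least 2-fold lower in the untreated KO colon.

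Markers of position along the gut differed between these arrays. Of 11 posterior Hox genes, 6 were at least 2-fold lower and 2 higher (Hoxb9 and Hoxd8) in KO, with a median of -1.31, at percentile 0 of 10000 random lists matched on expression. Of 12 small intestine and proximal colon markers, 6 were higher and 1 lower (Gsdmc2), with a median of 1.25 (percentile 100). Fabp2, a fatty acid binding protein of enterocytes, was higher by 3.90, the alkaline phosphatase gene Alpi by 3.75, the ileal bile acid transporter gene Slc10a2 by at least 3.25 and Hoxb6 by 3.35. Without the filter on dim probe sets, the posterior Hox median was 0.19.

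Several other lists were shifted in the untreated KO colon. Of 29 interferon-stimulated genes, 15 were at least 2-fold higher and 1 lower (Gbp2), with a median of 1.00 (percentile 100), and with Ifit2 at 2.16 and Irf7 at 1.80. Genes of MHC class II and antigen presentation had a median of 0.61 over 19 genes, with 1 higher (H2-DMa, 1.12) and 1 lower (H2-Ob, -2.94). Of 19 goblet cell genes, 10 were lower and 0 higher, with a median of -1.24, and with Capn9 at -2.27 and Fcgbp at -2.20. Of 16 B and plasma cell markers, 10 were lower and 0 higher, with a median of -1.15, and with Ms4a1 at -2.56 and Cd79b at -2.27. The medians were -0.93 for fetal-like repair genes, -0.60 for the antimicrobial list, -0.56 for colonocyte transport genes, 0.61 for fatty acid oxidation genes and 0.52 for xenobiotic genes. Markers of other cell types shifted as well, with medians of 0.465 for T and NK cell markers (13 higher, 3 lower) and 0.745 for adipocyte markers (8 higher, 2 lower). The inflammatory lists lay nearer 0, at 0.28 for neutrophil markers, 0.24 for chemokines, -0.08 for inflammatory cytokines and -0.21 for proteases and inhibitors, and proliferation genes at 0.12.

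**Figure D3:**
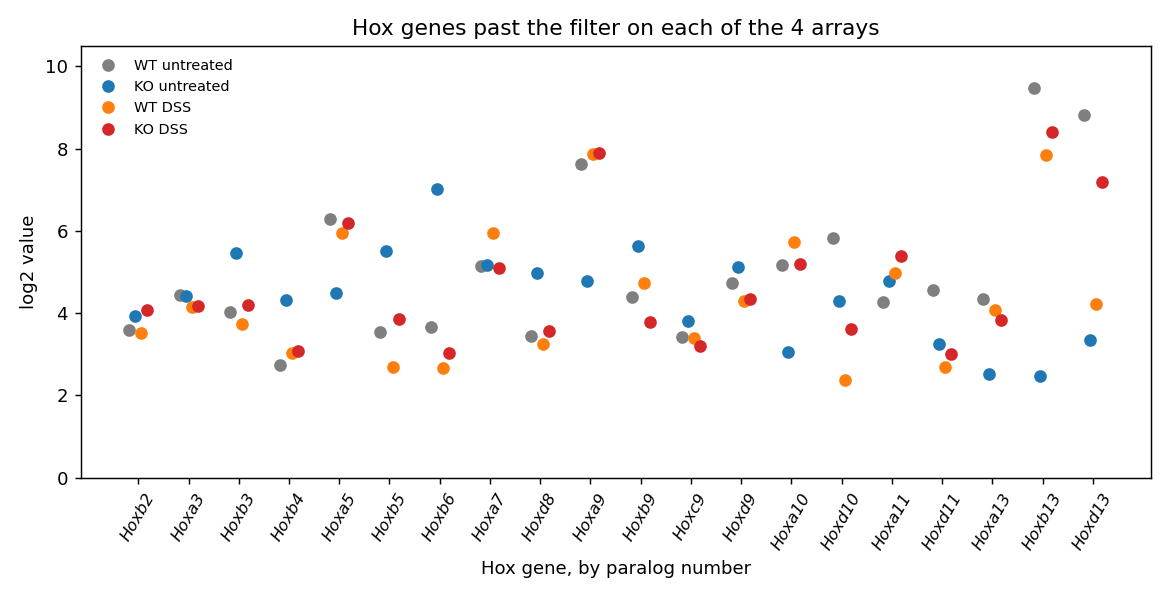
Log2 value of each of 20 Hox genes past the filter, ordered by paralog number, on each of the 4 arrays, with 1 point per array and so no error bars. Hoxb13 was at 2.48 on the untreated KO array and at 7.84 or above on the other 3 arrays, and Hoxd13 ranged from 3.36 on the untreated KO array to 8.82 on the untreated WT array.

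Among DSS-treated mice, the KO colon had higher levels of inflammatory transcripts than the WT colon. Il6, an inflammatory cytokine, was higher by at least 4.89 on the log2 scale, Chil1, a chitinase-like protein of inflamed epithelium and macrophages, by 4.57, and the collagenase gene Mmp13 by 3.67. The interferon-induced genes Gbp2b and Ifi44l were higher by 6.37 and at least 5.54. Xaf1 was higher by 4.49 on its brighter probe set and lower, at -1.05, on its other one. Tmem267 (4.18) and Nxpe4 (4.02) were also among the 8 highest. Reg3g (-4.43) and Reg3b (-4.05), lectins that act against bacteria, were among the lowest, with Sptssb (-5.72), the phospholipase gene Pla2g4c (-4.03), Hsd17b13 (-3.89), Fabp2 (-3.56), Slc3a1 (-3.35) and Aadac (-3.32). In all, 514 genes were at least 2-fold higher and 147 at least 2-fold lower.

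By list, 7 of 11 neutrophil markers were at least 2-fold higher in KO under DSS (median 1.11), as were 7 of 10 inflammatory cytokine genes (1.45), 13 of 24 chemokine genes (1.07) and 8 of 16 genes of proteases and inhibitors (1.13), and none of these lists had a member 2-fold lower. Some members, such as Il6 and Clec4d, passed the filter only through the KO DSS array and could not be lower there. S100a9 was higher by 3.43, the formyl peptide receptor gene Fpr2 by 2.92, Il11 by 2.78, the eosinophil chemokine gene Ccl11 by 2.65, Cxcl10 by 2.56 and Mmp3 by 2.75. Fetal-like repair genes had a median of 0.92 and fibroblast and fibrillar matrix genes of 0.69, with 7 of 16 and 7 of 24 members higher. Goblet cell genes were lower here too, 12 of 19 by at least 2-fold and 0 higher, with a median of -1.08. B and plasma cell markers were higher, 10 of 16 by at least 2-fold, with a median of 1.54 and with Ms4a1 at 2.57. Proliferation genes differed little, with a median of -0.13 and no member 2-fold apart. Posterior Hox genes had a median of 0.32, with Hoxd13 higher by 2.98 and Hoxd10 by 1.24, and small intestine and proximal colon markers of -0.26. The medians were 0.30 for interferon-stimulated genes, 0.50 for MHC class II genes, -0.30 for xenobiotic genes, -0.25 for fatty acid oxidation genes and -0.36 for colonocyte transport genes. The antimicrobial list had a median of 0.14, which turned to -0.26 without probe sets that can match several transcripts. The count of higher genes was 329 under the 75th percentile filter, which left 8046 genes, and 325 of the 329 were among the 514.

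**Figure D4:**
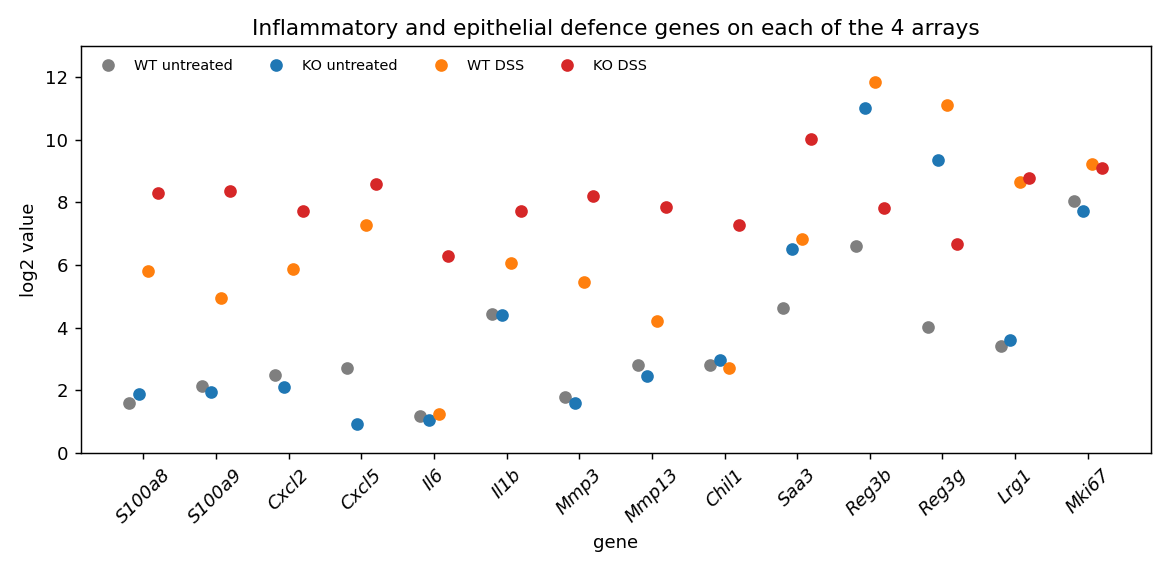
Log2 value of 14 inflammatory, epithelial defence and proliferation genes on each of the 4 arrays, with 1 point per array and so no error bars. Il6 was at 6.28 on the KO DSS array and at 1.24 or below on the other 3, Reg3g was at 11.10 on the WT DSS and 6.67 on the KO DSS array, and Lrg1 was at 8.65 and 8.78 on the DSS arrays.

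Genes that differed between KO and WT in the same direction with and without DSS were few. Higher in KO were Ifi44l (5.09 without and at least 5.54 with DSS), Gbp2b (3.67 and 6.37), Tmem87a (2.58 and 2.61), the acute-phase gene Saa3 (1.89 and 3.21), the interferon-inducible Ifi213 (3.0 and 1.95), the arginase gene Arg2 (3.20 and 1.57), Fpr2 (1.57 and 2.92), Akr1c19 (2.83 and 1.43) and Hoxd3os1 (2.82 and 1.07). Xaf1 (2.08 and 4.49) belonged to the same group, while its other probe set had a mean KO minus WT difference of -0.81. Lower in KO were Pla2g4c (-2.57 and -4.03), Ccn3 (-4.29 and -1.97), Insl5 (-5.12 and -1.02), the water channel gene Aqp8 (-3.74 and -1.27), Taf15 (-2.29 and -2.61), the lectin gene Itln1 (-3.48 and -1.27), the antimicrobial ribonuclease gene Ang4 (-1.48 and -2.54), Tnfsf13os (-2.24 and -1.78), Sycn (-2.84 and -1.17) and Gsdmc2 (-2.45 and -1.52). In total 24 genes were at least 2-fold higher under both treatments, against 17.6 for independent lists, and 29 were lower, against 8.80. More genes were lower without DSS and higher with it (106, against 30.8), and 47 went the other way (against 5.04). Across genes the KO minus WT differences without and with DSS correlated at r = -0.224 (Spearman's rho = -0.262).

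In limma's model, 0 genes passed the test of KO against WT, with 175 at an unadjusted p under 0.05 (81 higher, 94 lower) where 609 would be found by chance. With 1 array left out there were 45 to 632, so this number depended on single arrays. The smallest adjusted p was 0.9995 (0.0748 to 1.0 over the alternatives), and the smallest unadjusted p belonged to Ifi44l (log2 difference 5.33 on the measured values, SE 0.29, higher under both treatments). Adjusted over the list alone, the goblet cell genes Clca1, Fcgbp, Spink4, Ang4, Retnlb and Capn9 were lower in KO, and in the antimicrobial list Saa3 was higher and Ang4 and Retnlb lower. Clca1, a secreted mucus component, differed by -1.72 without and -1.22 with DSS, and Spink4 by -2.10 and -1.08. No member of the other lists passed. The untreated KO array, which stood apart in position markers, enters this test too.

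The DSS difference itself diverged between the genotypes for 2225 genes by at least 2-fold, 1503 of them more positive in KO and 722 more negative. Among the 8 most positive and the 8 most negative divergences were Sptssb (5.16 in WT and -6.69 in KO), Reg3g (7.09 and -2.70), Cyp2c65 (0.95 and -7.91), Reg3b (5.26 and -3.20), Hoxd13 (-4.60 and 3.84), Slc3a1 (3.47 and -4.50), Slc13a1 (2.30 and -5.64), Sval1 (-1.97 and 5.82), Cyp2c55 (-1.56 and -9.12), Hoxb13 (-1.63 and 5.92), Fabp2 (1.35 and -6.11), Reg4 (-4.79 and 2.39), Mptx1 (-1.82 and 5.32) and Atp12a (-0.73 and 5.96). The immunoglobulin gene Ighv14-2 (-2.10 and 4.34) and H2-Ob (-2.39 and 3.77), an antigen presentation gene of B cells, made up the rest of these 16. These differences could not be tested with 1 array per group. Halved, to put them on the scale of the mean DSS and genotype differences, they had a robust SD over genes of 0.337, against 0.441 for DSS and 0.248 for genotype. The untreated KO array, which stood apart in position markers, enters every value.

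Other cell types, neighbouring tissue and handling genes were examined with lists of their own. B and plasma cell markers were lower with DSS in WT (11 of 16 by at least 2-fold, median -1.25) and higher in KO (12 of 16, median 1.59). Enteric neuron and glia genes had DSS medians of 0.08 in WT and 1.25 in KO over 18 genes, and KO minus WT medians of -0.57 without and 0.58 with DSS. Smooth muscle genes had DSS medians of -0.62 and 0.33 over 19 genes, and KO minus WT medians of -0.74 and 0.13. Fibroblast genes had DSS medians of -0.04 and 0.94, and a KO minus WT median of -0.20 without DSS. With DSS, T and NK cell markers had medians of -0.08 in WT and -0.44 in KO, macrophage and monocyte markers of -0.18 and 0.21, mast cell and eosinophil markers of 0.42 and 1.32, endothelial and lymphatic markers of 0.00 and 0.74, and adipocyte markers of 0.54 and -0.20. Posterior Hox genes had DSS medians of -0.28 and -0.24, small intestine and proximal colon markers of -0.45 and -1.5, and squamous epithelium markers of the anal canal, with 5 genes measured, of 0.18 and -0.04. Interferon-stimulated genes had DSS medians of -0.13 in WT and -0.78 in KO, and MHC class II genes of -0.39 and -0.42.

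Among the remaining lists, DSS medians were 0.67 in WT and 0.31 in KO for heat shock genes, 0.16 and 1.07 for immediate-early genes, -0.73 and -0.30 for circadian clock genes, 0.07 and 0.19 for endoplasmic reticulum stress genes, and -0.10 and 0.43 for apoptosis regulators. They were -0.02 and -0.56 for oxidative phosphorylation genes, 0.02 and -0.26 for intestinal stem cell and crypt genes, -0.27 and -0.15 for tight junction genes, and -0.10 and -0.02 for enteroendocrine cell genes. The 12 measured members of the ADAMTS family had medians of 0.03 and -0.09, with Adamts4 higher by 1.93 and 1.51 and Adamts1 by 0.71 and 2.76. The 17 genes near Adamts12 on chromosome 15 had KO minus WT medians of -0.34 without and 0.02 with DSS. Housekeeping genes had DSS medians of 0.21 and 0.26, and KO minus WT medians of 0.02 and 0.03. The sex-linked list had 1 gene past the filter, Xist, which was bright on all 4 arrays, while 9 Y-linked probe sets lay between 0.51 and 1.39.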

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

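Of the tests in this part, only the comparison of brightness was set before its result was seen, and all others were chosen afterwards. The difference of the DSS effect between KO and WT had opposite signs in the genotypes, each at least 2-fold, for 18 of the genes named by a ranking, and it could not be tested with 1 array per group. It was 8.44 for Hoxd13, 7.79 for Sval1, 7.55 for Hoxb13, 7.18 for Reg4, 7.14 for Mptx1, 6.44 for Ighv14-2, 6.16 for H2-Ob, 5.56 for Tgm3, 4.43 for Tmem267 and 2.70 for Gbp2b. It was -11.85 for Sptssb, -9.79 for Reg3g, -8.46 for Reg3b, -7.97 for Slc3a1, -7.94 for Slc13a1, -7.46 for Fabp2, -7.23 for Isx and -3.47 for Aadac.

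Several lists had medians on opposite sides of 0 in the compared groups, which was not tested. The median over members of the difference of the KO effect with and without DSS was 2.74 for B and plasma cell markers, which also parted by DSS effect, 1.61 for fetal-like repair genes, 1.60 for posterior Hox genes, 1.27 for enteric neuron and glia genes, 0.99 for smooth muscle genes and 0.62 for the antimicrobial list. It was -0.91 for fatty acid oxidation genes, -0.75 for small intestine and proximal colon markers, -0.53 for oxidative phosphorylation genes and -0.49 for xenobiotic genes.

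The untreated KO array differed from the other arrays in genes that mark position along the colon. Array scaling or brightness was examined with 747 genes as bright on the untreated WT array as the 8 lowest named genes. They had a median KO minus WT difference of -0.17 (5th to 95th percentile -1.74 to 0.61), against -5.12 to -7.96 for those 8. The deposited columns had nearly equal quantiles and the 8 were chosen as the lowest, so this contrast was largely fixed beforehand. It shows no shift of all bright genes and does not decide about brightness otherwise. The hybridization and poly-A controls were lowest on the untreated KO array, by medians of -0.66 and -1.40 against the untreated WT array. Of the 16 named genes, 1 was at least 2-fold apart the same way under DSS and 5 were apart the opposite way, so most of these differences did not recur. The 16 were chosen as extremes of the untreated pair, and an effect of Adamts12 loss need not persist under DSS. This count therefore does not decide about a lasting effect of Adamts12 loss. Tissue taken nearer the caecum may account for the values of the untreated KO array. Its difference from the mean of the other 3 correlated with Hox paralog number over 20 Hox genes, which are not independent replicates (rho = -0.562). Without Hoxb13 and Hoxd13 rho was -0.41, and the untreated WT array deviated the other way (rho = 0.558). With DSS in WT, 4 of 11 posterior Hox genes were at least 2-fold lower and 0 higher, with Hoxd13 at -4.60 and Hoxd10 at -3.45. Whether position also enters the DSS difference in WT was not tested. An effect of Adamts12 loss limited to the untreated colon stays open, since there is 1 untreated KO array.

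Inflammatory genes were higher on the KO than on the WT DSS array, with 34 of 59 genes of the neutrophil, chemokine, cytokine and protease lists at least 2-fold higher, 0 lower and a median of 1.15. Members such as Il6, Csf3 and Clec4d passed the filter only through the KO DSS array, so they could not be lower there. The filter kept 10 of 21 cytokine genes and 11 of 17 neutrophil markers with a probe set. The absence of lower genes was thus partly fixed by the filter. A lower share of epithelium would raise all other cell types alike. The neutrophil median exceeded the T and NK cell median by 0.995, with a bootstrap interval over genes of 0.055 to 2.40 that barely leaves out 0 (2.4% of draws lay at or under 0). The T and NK cell median, 0.115, was the lowest of 9 non-epithelial lists, and this pair was chosen after the values were seen. Genes are no replicates of mice, so the interval does not decide whether a lower share of epithelium is the whole cause. A lower share of epithelium may account for part, as 19 of 19 goblet cell and 22 of 30 colonocyte transport genes were lower. Higher were 18 of 18 endothelial, 23 of 24 fibroblast, 17 of 18 neuron and glia and 16 of 16 B cell genes. T and NK cell markers (9 higher, 5 lower), smooth muscle genes (14 and 5, median 0.13) and macrophage markers (17 and 4, median 0.30) were shifted less. Other epithelial lists did not all fall, with tight junction genes at a median of -0.19 (6 higher, 11 lower) and fetal-like repair genes at 0.92 (14 and 2). Between the untreated arrays, 16 of 19 goblet cell genes and 16 of 16 B cell genes were lower in KO. The goblet cell difference alone is thus no measure of the share of epithelium. A baseline difference between colon positions stays open, since the untreated arrays, with a median of 0.06 over the 59 genes (quartiles -0.24 to 0.54), come from other mice at positions not known, as does a stronger response nearer the anus (Hox rho 0.0288 over genes, posterior Hox median 0.32, Hoxd13 2.98 higher). Such effects of position cannot be told apart from a stronger response to DSS without Adamts12 or from a chance difference in severity between 2 mice, since there is 1 array per group.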

How the results depend on the processing

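The settings were planned except the comparisons of KO arrays with the other WT array, which were chosen after seeing the data. Of 87 comparisons of a main result with an alternative, 82 stayed within 1.5 times of the count, or on the same side of the threshold, and 5 did not. The 82 include comparisons of 0 with 0 genes in the limma tests, which say little about stability. Genes at least 2-fold higher in KO than in WT under DSS numbered 329 with the 75th percentile filter, which tests fewer genes, against 514. Genes at least 2-fold higher with DSS in KO numbered 748 when the untreated WT array was the baseline, against 1312, and 537 were shared. The Adamts12 difference, averaged over both treatments, was -0.42 with the mean over probe sets, against -0.77, and is no measure of the gene, since it averages in the probe set that is not above background. The DSS test called 1 gene, Lrg1, with quantile normalization (adjusted p = 0.0373) and 1 without the covariate (adjusted p = 0.0336), against 0, and the smallest adjusted p ranged from 0.0336 to 0.662 over the alternatives. For KO against WT it was 0.0748 with quantile normalization, 0.157 without the covariate and 0.380 with the mean over probe sets, against 0.9995, with 0 genes past the test in each. Leaving out each array in turn, without the covariate and with the lone array assumed to vary like the others, gave 0 to 0 genes for DSS and 0 to 0 genes for KO. The genes at an unadjusted p under 0.05 were less stable. For DSS they numbered 2695 without the untreated WT, 2018 without the untreated KO, 1111 without the WT DSS and 901 without the KO DSS array, against 1437. For KO they numbered 45, 434, 178 and 632 in that order, against 175, where 609 would be found by chance.

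Of 908 list medians, 774 kept their value within the spread of random lists, 132 moved further and 2 reversed. The antimicrobial list, KO against WT under DSS, was -0.26 without probe sets that can match several transcripts, and posterior Hox genes, KO against WT untreated, were 0.19 with no filter, which adds dim members to a list whose members went both ways; the cause was not tested further. Of 536 values of named genes, 514 stayed and 22 moved, with no change of sign. No paired analysis was possible because each group holds 1 array and the labels share no other number. A floor and a pseudocount were not run because the values are on a log scale, and filters give no value for Adamts12, which lies below them. The 2-fold threshold added to the limma tests changes nothing at 0 calls. For dim genes such as Adamts12 the signal over background limits what can be read from a difference.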

Other observations

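The tests in this part were all chosen after the result was seen. The genes Meg3, Dlk1 and Rian of an imprinted cluster, singled out after their values were seen, were lower in both KO mice. Meg3, a long noncoding RNA, differed from WT by -1.60 without and -2.12 with DSS, Dlk1 by -1.65 and -2.0, and Rian by -0.66 and -1.83. At least 1 other kept probe set of Meg3 was not 2-fold lower under both treatments. The DSS differences were 1.82 in WT and 1.30 in KO for Meg3, 1.00 and 0.65 for Dlk1, and 1.87 and 0.70 for Rian.

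Hormone genes of enteroendocrine cells went different ways in the untreated KO colon, where the neurotensin gene Nts was higher by 5.65 and Insl5 lower, at -5.12. With DSS in KO, Nts differed by -5.44 and Insl5 by 3.27. The adipocyte gene Adipoq was higher with DSS in WT by 2.51 and lower in KO, at -2.40. Among endothelial genes, the adhesion molecule genes Selp, Icam1 and Vcam1 were higher on the KO than on the WT DSS array by 2.95, 1.5 and 1.48.

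Across both treatments, 53 genes were at least 2-fold apart between KO and WT in the same direction, 24 higher and 29 lower. Of the 53, 0 lay among the 79 tested genes nearest to Adamts12, where 0.34 would by chance. No gene of the group thus lies in DNA that close to Adamts12 carried along from a donor strain. Donor DNA elsewhere, or acting on distant genes, was not tested, so donor DNA as a cause stays open. Sequence or transcript differences under single probe sets may account for some, since 40% of the 15 genes with another kept probe set (Cxcl9, Iigp1, Meg3, Pla2g4c, Socs3 and Xaf1) had one that did not show the difference, but the share was 58.9% of 185 genes apart with DSS in both genotypes. A wider interferon response in both KO mice stays open: the whole list had medians of 1.00 and 0.30, both at percentile 100, but with DSS its members went both ways, 17 higher and 12 lower, and 5 of the 29 are themselves among the 53 genes. Position along the colon and the mix of cells were not tested for the 53 and stay open too. The 53 include the proximal markers Hoxb5 (1.97 without and 1.18 with DSS) and Gsdmc2, which was lower (-2.45 and -1.52). Goblet cell genes such as Clca1, Fcgbp and Spink4 are also among them. The untreated KO array, which stood apart in position markers, enters the choice of all 53.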
